A study of Mus musculus with 6 samples.

How the data were processed

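RNA was measured by sequencing of polyadenylated RNA from the pancreas of 8-week-old mice, in 3 wild-type (WT) and 3 Ela1-Myc libraries. Per the labels' protocols, total RNA was extracted with phenol and chloroform, mixed with ERCC spike-in RNA, made into stranded libraries by the dUTP method and sequenced on a Genome Analyzer IIx. The protocol text states an RNA integrity number (RIN) above 8.5 for the samples used, and the RIN given with the samples lies below that for 5 of the 6 libraries: 7.3, 7.3 and 7.1 in WT replicates 1 to 3, and 8.8, 7.2 and 8.3 in Ela1-Myc replicates 1 to 3. Which of these statements holds is open.

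The deposited files give 1 value per gene and library, headed as an adjusted FPKM (fragments per kilobase of transcript, relative to all mapped fragments) per the file headers. CASAVA 1.8, FastQC 0.9.4, TopHat2 2.0.4, Bowtie, Cufflinks 2.0.2 and affy are named, per the submitters' processing notes, with the mouse build GRCm38 (mm10). How the FPKM values were adjusted is not given in the sources used here. The deposited values lie far above the usual FPKM range, so all values of all libraries were divided by a single constant, 100000, after which they sum to between 629597 and 1948844 per library. That constant was chosen after the files had been seen and before any test, because the pseudocount and the filter had been fixed for the usual FPKM scale; printed values are on the divided scale. Ratios between libraries and genes are not touched by it, but the pseudocount's effect is, and a pseudocount of 1 on the deposited scale was run as an alternative.

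Several features of the deposited values limit what they can show. An exact 0 is not evidence of absence: genes that every cell uses, such as the glycolytic gene Gapdh, stand at 0 in WT replicates 1 and 3. Among the 8802 tested genes, 1061, 592 and 1426 are at 0 in WT replicates 1 to 3, against 0, 29 and 13 in Ela1-Myc replicates 1 to 3. In addition, 4459 of the 23422 rows share 1 identical value within each WT library (464, 822.5 and 173.9 on the deposited scale, within 1e-06) and are 0 in every Ela1-Myc library. How these values came about is not given in the sources used here. Single genes with a 0 are therefore described as listed at 0 and given without a mean or a fold, while the medians and tests of gene lists include such genes. Read counts and spike-in rows were not used here, so the depth of each library is unknown, and no counting interval or detection limit is given.

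The 23422 rows carry 23099 gene symbols, and for the 187 symbols with several rows the row with the highest mean was kept. Genes with a mean of at least 1 over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with an intensity trend in the variance, two-sided, at a Benjamini-Hochberg adjusted p of 0.05. A gene listed at 0 in most WT libraries passes this filter largely through its Ela1-Myc values, so its direction is largely fixed by the filter. This bears on the mitosis, replication, MYC target, ribosome biogenesis, macrophage, inflammatory and lymphocyte lists and on others with many listed zeros. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The model held the group only. Nothing states that the libraries of a group came from separate animals, so p-values measure the spread between these samples. For genes with a 0, the limma p-values take the listed zeros as measured values. Single measures per library were compared by an exact two-sided permutation test, whose smallest p with 3 against 3 libraries is 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

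There were 35 gene lists, fixed from textbook knowledge before the data were examined; none was chosen on these samples. Of their 954 entries 939 matched a symbol in the files, 5 of them through a synonym, and 34 lists had at least 3 tested members. Lists were tested with camera (limma) at its preset correlation of 0.01 between genes, adjusted over the 34 lists. Camera asks whether a list's test statistics differ from those of the other genes. A list whose members rose with smaller statistics than other genes is therefore called lower, even where its median log2 change is above that of the median gene. Fry asks whether a list's own genes changed, and its p and direction do not bear on camera's question. Beside it stand the count of members called over all genes and the count adjusted over the list alone. Many genes share reads with close copies, among them the trypsinogen, amylase and kallikrein families, ribosomal proteins and globins, and their single values are uncertain.

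The genes named follow a rule fixed before the data were examined. Part 1 is a set of 28 genes named whatever their result. Part 2 is the 12 largest increases and 12 largest decreases past the threshold with all 3 Ela1-Myc values on one side of all 3 WT values and a mean of at least 5 in the higher group; 10 decreases qualified. Part 3 is up to 4 members of each list in its majority direction and up to 2 in the other, or 2 where none was called. A further group, the 10 largest changes in each direction after median-of-ratios scaling among genes above 0 in all 6 libraries, was chosen after the values had been seen. Part 2 is named in full, and part 1 apart from 1 gene that is left out of the text; of part 3 and of the further group the text names some genes, picked after the values had been seen.

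Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter, a minimum mean of 5, median-of-ratios scaling, quantile normalization, removal of the digestive enzyme list with equal totals, robust and array-weighted fits, RIN as a covariate, each library left out, an estimated correlation in camera, and fry. Added after the data were seen were the pseudocount on the deposited scale, the restriction to genes above 0 in all 6 libraries alone and with scaling, zeros as missing values, removal of 115 small RNA genes, scaling with an estimated correlation, and scaling without WT replicate 2. Median-of-ratios scaling changes the division into higher and lower genes and is printed beside the main gene counts and list tests. The pipeline was tested on simulated values for this comparison with 8802 genes: of 50 genes changed by 1, 2, 3 and 4 log2 units, 8%, 58%, 90% and 86% were called, and 3.97% of the calls were unchanged genes. The simulated genes varied independently, few were changed, and as many were raised as lowered. There were no listed zeros and no differences in scale between libraries, so these rates do not carry over to the real values. Gene positions are those of the files, in GRCm38, written 1-based; of 8063 tested symbols found in GENCODE vM21, 99.76% overlap the gene of that name.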

Results

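Whole-pancreas transcriptomes of 8-week-old mice were profiled by stranded RNA-seq in 3 wild-type (WT) libraries and 3 libraries from Ela1-Myc mice, a line that carries Myc under the promoter of elastase 1, a gene of the enzyme-secreting acinar cells. Myc encodes a transcription factor that drives growth and division. The single comparison of the design, Ela1-Myc against WT, addresses how the adult pancreas differs when Myc remains active in acinar cells. Values are the authors' adjusted FPKM divided by 100000, and the depth of each library is unknown. RIN was 7.23 ± 0.115 (SD, n = 3) in WT and 8.1 ± 0.819 (SD, n = 3) in Ela1-Myc.

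Myc itself (chromosome 15, 61985341 to 61990361, GRCm38) was at 52.0, 34.4 and 34.2 in Ela1-Myc replicates 1 to 3 and at 4.10 in WT replicate 2, and it was listed at 0 in WT replicates 1 and 3. All 3 Ela1-Myc libraries lay above all 3 WT libraries (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give; limma adjusted p = 4.97e-05). After median-of-ratios scaling the call stood at an adjusted p of 0.0102. The limma p-values take the listed zeros as measured values. The values do not separate transcripts of the transgene from those of the mouse's own gene.

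The digestive enzyme list took a smaller share of the summed adjusted values in Ela1-Myc than in WT. The 34 genes of the digestive enzyme and zymogen list that the files hold made up 89.8% ± 0.239 (SD, n = 3) of the summed values in WT and 67.0% ± 6.31 (SD, n = 3) in Ela1-Myc (exact two-sided permutation p = 0.1). The single libraries stood at 89.6%, 89.7% and 90.0% in WT and at 72.4%, 60.1% and 68.6% in Ela1-Myc. The summed values of all other genes were 129000 ± 65900 in WT and 263300 ± 32700 in Ela1-Myc (SD, n = 3 each; exact permutation p = 0.1), while the enzymes' own sum, 1137000 ± 578000 in WT and 562300 ± 208000 in Ela1-Myc, and the library totals did not separate the groups (exact permutation p = 0.2 and 0.3). Tested genes listed at 0 numbered 1061, 592 and 1426 in the WT libraries and 0, 29 and 13 in the Ela1-Myc libraries. A gene listed at 0 adds nothing to the sum of other genes. How far the zeros raise the enzyme share in WT is therefore unknown.

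**Figure D1:**
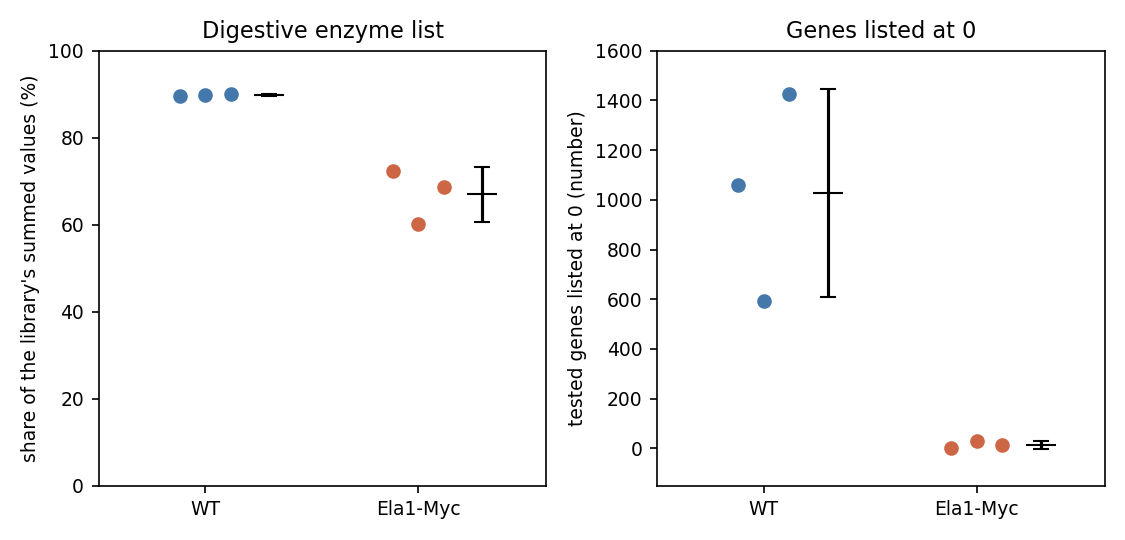
Left, share of each library's summed values taken by the digestive enzyme list (%); right, number of the 8802 tested genes listed at 0. Each coloured point is 1 library and the black bar is the mean ± SD of the 3 libraries of a group; enzyme shares lie between 60.1% and 72.4% in Ela1-Myc and between 89.6% and 90.0% in WT.

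Most tested genes were higher in Ela1-Myc on the deposited scale. Of 8802 genes, 6203 changed, 6182 of them higher and 21 lower, and 5207 changed at least 2-fold; the median gene lay 1.22 log2 units higher. This division rests on the scale. After median-of-ratios scaling, which moved the median gene to 0.23, 2320 genes changed, 1614 higher (69.6%) and 706 lower (30.4%), against 99.7% and 0.339% on the deposited scale. Quantile normalization gave 996 higher and 1758 lower genes, and removal of the enzyme list with equal totals gave 2123 higher and 302 lower. Without WT replicate 1, 2 or 3 the lower genes numbered 62, 12 and 7, and without Ela1-Myc replicate 1, 2 or 3 they numbered 7, 5 and 5. Of the 6182 higher genes, 1737 were listed at 0 in at least 1 WT library. All 3 Ela1-Myc values lay above all 3 WT values for 6630 genes and below them for 47, where chance gives 10% of genes in the sum of both directions; after scaling these numbers were 2674 and 1511. Each gene group is therefore given on both scales.

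Enzymes of protein, fat and nucleic acid digestion were lower for a minority of the list on the deposited scale and for most of it after scaling. On the deposited scale 12 of the 33 tested members of the list were lower, 4 higher and 17 not called (8 lower and 4 higher adjusted over the list alone), with a median log2 change of -0.98. After scaling 25 were lower and 3 higher, with a median of -2.50, and among the 29 members above 0 in all 6 libraries 28 were lower. Under quantile normalization 9 were lower and 6 higher, the median was -0.357 and the camera call was lost (adjusted p = 0.271). Pancreatic lipase Pnlip (chromosome 19, 58670365 to 58681788) went from 75730 ± 39130 to 25190 ± 7103 (SD, n = 3 each), a log2 change of -1.50 ± 0.378 (SE; adjusted p = 0.0035), or -3.02 ± 0.215 after scaling. The elastases Cela1 (chromosome 15, 100674422 to 100687920) and Cela2a (chromosome 4, 141814963 to 141826003) fell by 1.39 and 1.40 log2 units (adjusted p = 0.00488 and 0.00535), and by 2.91 and 2.92 after scaling. Pancreatic ribonuclease Rnase1 fell by 1.34, the zymogen granule proteins Zg16 and Sycn by 1.36 and 1.30, tissue kallikrein Klk1 by 1.26, carboxypeptidase Cpa1 by 1.14 and carboxyl ester lipase Cel by 1.09 log2 units; after scaling their changes were -2.86, -2.88, -2.82, -2.78, -2.65 and -2.61. Chymotrypsinogen Ctrb1 and trypsinogen Prss2 did not pass on the deposited scale, with log2 changes of -0.68 and -0.72 (adjusted p = 0.0955 and 0.136), and passed after scaling with -2.20 and -2.24. The 4 members called higher were amylase and trypsinogen copies that were listed at 0 in WT replicates 1 and 3, and reads of such copies are hard to place. Amy2a5 stood at 70.4 in WT replicate 2 and at 1665, 1421 and 1278 in Ela1-Myc, and Amy2b at 8.44 and at 332.7, 296.5 and 283.9. Prss1 stood at 736.2 in WT replicate 2 and at 4098, 4426 and 2766 in Ela1-Myc, and Prss3 at 329.8 and at 8787, 3458 and 2589. On the deposited scale the lower members numbered 21, 0 and 3 without WT replicate 1, 2 or 3 and 7, 5 and 5 without Ela1-Myc replicate 1, 2 or 3; after scaling and without WT replicate 2 they numbered 24. Camera placed the list below the other genes (adjusted p = 1.31e-41; 7.49e-18 after scaling), but not with an estimated correlation (adjusted p = 0.813; 0.467 after scaling).

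Transcription factors of the acinar programme were called lower only relative to other genes. On the deposited scale 2 of 11 members were higher, none was lower and 9 were not called (0 in either direction adjusted over the list alone), with a median log2 change of 0.07; after scaling 6 were lower, none higher, and the median was -1.27. Rbpjl, the acinar partner of Ptf1a in the PTF1 complex, was at 38.7 ± 20.6 in WT and 32.8 ± 9.74 in Ela1-Myc (SD, n = 3 each), with a log2 change of -0.15 ± 0.691 (SE; adjusted p = 0.844) that became -1.62 ± 0.308 after scaling (adjusted p = 0.0129). Bhlha15 (Mist1), which organises the secretory apparatus, showed -0.21 (adjusted p = 0.782) and -1.66 after scaling (adjusted p = 0.012). Gata6 turned from 0.07 (adjusted p = 0.832) to -1.005 after scaling (adjusted p = 0.0158). Ptf1a, the master factor of acinar fate, turned from 0.15 to -1.27 and Nr5a2 from 0.45 to -0.64, and neither passed on either scale (adjusted p = 0.835 and 0.308; 0.0677 and 0.13 after scaling); both were called lower under quantile normalization (adjusted p = 0.0449 and 0.0415), Ptf1a also after scaling among genes above 0 in all 6 libraries (0.0426), and Nr5a2 was called higher with array weights (0.0211). Gata4 and Foxp1 were the 2 called higher, by 1.21 and 0.86 log2 units (adjusted p = 0.045 and 0.0112), and lay at -0.02 and 0.02 after scaling. Camera placed the list below other genes (adjusted p = 2.53e-06; 3.39e-05 after scaling; 0.813 and 0.467 with an estimated correlation), although its deposited-scale median lay just above 0.

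No single gene of regulated secretion was called lower on the deposited scale, while several were on other scales. Of 20 tested genes for acinar secretion and cell coupling, 6 were higher and none lower on the deposited scale (4 higher adjusted over the list alone; median -0.12), and 10 were lower and none higher after scaling (median -1.14). Under quantile normalization 13 were lower, and with the enzyme list left out 9 were lower, with none higher in either. The gap junction gene Gjb1, through which acinar cells are coupled, was at 18.1 ± 10.8 in WT and 11.96 ± 1.68 in Ela1-Myc (SD, n = 3 each), with a log2 change of -0.41 (adjusted p = 0.517) and -1.81 after scaling (adjusted p = 0.00415). The exocytosis genes Snap23 and Stxbp2, the calcium channel Itpr3 and the water channel Aqp8 were higher by 1.25, 1.48, 1.01 and 2.01 log2 units on the deposited scale, and none of the 4 passed after scaling. Camera gave adjusted p = 4.08e-11 for the list lying below other genes (4.09e-07 after scaling; 0.813 with an estimated correlation).

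Genes for entry into the endoplasmic reticulum (ER), ER chaperones and the amino acid stress response were mostly not called. Higher members numbered 9 of 36 in the secretory pathway list (3 adjusted over the list alone), 12 of 29 in the ER chaperone and unfolded protein response list (11) and 6 of 22 in the ATF4 list (5), with none lower and medians of 1.04, 1.05 and 0.60. After scaling 6, 8 and 4 were lower and 1, 1 and 3 higher, and the medians turned to -0.37, -0.10 and -0.61; the ER chaperone median was 0.17 when the enzyme list was left out. Camera placed all 3 lists below other genes (adjusted p = 6.8e-05, 0.000145 and 0.000191; 0.000677, 0.00836 and 0.0217 after scaling; 0.817 for each with an estimated correlation), while their deposited-scale medians were above 0; without WT replicate 2 the secretory pathway and ER chaperone lists lost the call (adjusted p = 0.901, on the other side, and 0.453). Hspa5, the main ER chaperone, was at 21.7, 203.9 and 7.29 in WT and at 294.4, 143.2 and 175.9 in Ela1-Myc (adjusted p = 0.0405; 0.416 after scaling). The KDEL receptor Kdelr2 and the translocon gene Ssr1 were higher by 1.77 and 2.44 log2 units (adjusted p = 0.0135 and 0.00149), and neither passed after scaling. The stress genes Ddit3, Ddit4 and Atf3 were listed at 0 in WT replicates 1 and 3, Atf3 also in WT replicate 2, and passed on both scales; Ddit3 stood at 0.965 in WT replicate 2 and at 18.6, 4.87 and 4.02 in Ela1-Myc.

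Ribosome biogenesis genes were higher without exception on the deposited scale. All 50 tested members of the ribosome biogenesis and nucleolus list rose (50 adjusted over the list alone), with a median of 2.23; after scaling 44 were higher, none lower, and the median was 1.52. Under quantile normalization 35 were higher and none lower. Of the 50 members, 35 were listed at 0 in at least 1 WT library and 23 in at least 2, where the filter largely fixed the direction. Among the 15 above 0 in all 6 libraries, 10 were higher after scaling and none lower. Nucleolin Ncl was at 18.4, 18.0 and 26.5 in Ela1-Myc and at 2.66 in WT replicate 2, and listed at 0 in WT replicates 1 and 3. The snoRNP core gene Nop58 and the nucleolar genes Nolc1, Rrp9 and Ddx21 were listed at 0 in the same WT replicates, stood between 0.165 and 0.716 in WT replicate 2 and between 6.76 and 12.1 in Ela1-Myc. Camera gave adjusted p = 7.99e-13 (1.72e-13 after scaling; 0.813 and 0.467 with an estimated correlation).

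Translation genes were called in part on the deposited scale, and few of them passed after scaling. Cytosolic ribosomal proteins numbered 38 higher of 66 (30 adjusted over the list alone; median 2.03) and 1 higher after scaling (median 0.51). Translation initiation and elongation factors numbered 24 of 30 (24; median 2.19) and 3 higher with 1 lower after scaling, and aminoacyl-tRNA synthetases 11 of 20 (11; median 2.02) and 3 higher with 1 lower. Camera did not place any of these 3 lists apart from other genes on the deposited scale or after scaling. Single libraries changed this. Without WT replicate 2 translation factors and synthetases lay above other genes (adjusted p = 0.000556 and 0.0266). After scaling without WT replicate 2, translation factors and ribosomal proteins did (0.00707 and 0.0406). Without Ela1-Myc replicate 1 or 2 ribosomal proteins lay below other genes on the deposited scale (0.00357 and 0.000997). Rpl30, the 1 ribosomal protein gene called higher after scaling, rose from 0.458 ± 0.416 to 5.92 ± 1.58 (SD, n = 3 each), by 2.26 log2 units (adjusted p = 8.23e-05, and 0.0295 after scaling). Its values were low beside Rps19, which stood at 732.9, 675.7 and 490.9 in Ela1-Myc and was not called after scaling (adjusted p = 0.11). The aspartyl-tRNA synthetase Dars rose by 2.23 log2 units (adjusted p = 0.000355, and 0.0273 after scaling).

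Established MYC target genes were mostly higher. Of 43 tested members 38 rose, none fell and 5 were not called (38 adjusted over the list alone; median 3.28); after scaling 28 were higher and 1 lower (median 2.36). Of the 43 members, 28 were listed at 0 in at least 1 WT library and 26 in at least 2. Those 26 met the filter largely through their Ela1-Myc values, so their direction was largely fixed in advance. Among the 15 above 0 in all 6 libraries, 4 were higher and 1 lower after scaling, with a median of 0.846. The helicase gene Ruvbl2 and the replication licensing gene Mcm7 were listed at 0 in WT replicates 1 and 3, stood at 0.389 and 0.517 in WT replicate 2, and at 13.2, 17.6 and 13.5 and at 13.8, 18.6 and 15.2 in Ela1-Myc. Shmt1, a gene of folate metabolism, was listed at 0 in all 3 WT libraries and stood at 6.14, 8.55 and 7.25 in Ela1-Myc. Ornithine decarboxylase Odc1, a classical MYC target, was not called: 36.8 ± 25.5 in WT and 74.6 ± 32.4 in Ela1-Myc (SD, n = 3 each), with a log2 change of 1.10 (adjusted p = 0.196) that turned to -0.38 after scaling (adjusted p = 0.498); it was called higher with array weights (adjusted p = 0.00197) and without WT replicate 2 (0.0103). Camera gave adjusted p = 2.53e-06 for the list (3.59e-07 after scaling; 0.817 with an estimated correlation), and 0.0661 after scaling when only the 15 members above 0 in all 6 libraries were kept. In the MYC and MAX network 4 of 8 members were higher (4 adjusted over the list alone), and after scaling 1 was higher and 1 lower, with no camera call on either scale; the MYC partner Max rose by 1.98 log2 units (adjusted p = 0.00243; 0.133 after scaling).

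Cell division genes were called higher on both scales, against WT values that were mostly listed at 0. All 28 tested genes of DNA replication and G1/S and all 21 of mitosis and G2/M passed on the deposited scale and after scaling, with the same counts adjusted over the list alone; quantile normalization kept 26 and 17 higher and none lower. All 21 mitosis genes and 22 of the 28 replication genes were listed at 0 in at least 2 WT libraries, so the size of these increases is unknown. The files hold 39 replication and 35 mitosis members, of which only those with a mean of at least 1 were tested. Genes at 0 in WT meet that mean largely through their Ela1-Myc values. That the tested members were higher was therefore largely fixed in advance. Above 0 in all 6 libraries were 4 replication genes, all 4 higher after scaling, and no mitosis gene. The proliferation marker Mki67, listed at 0 in all 3 WT libraries, stood at 3.25, 3.29 and 4.72 in Ela1-Myc (adjusted p = 1.51e-05; 0.00128 after scaling). Its WT spread is that of listed zeros, so these p-values do not rest on a measured spread in WT. The mitotic genes Birc5, Cdc20 and Ube2c and the replication genes Mcm6, Fen1 and Ccna2 were likewise listed at 0 in all 3 WT libraries; Birc5 stood at 16.6, 26.1 and 20.7 and Mcm6 at 9.05, 11.5 and 14.1 in Ela1-Myc. Camera gave adjusted p = 1.99e-14 for replication and 5.01e-14 for mitosis (7.86e-14 each after scaling; 0.813 each with an estimated correlation).

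**Figure D2:**
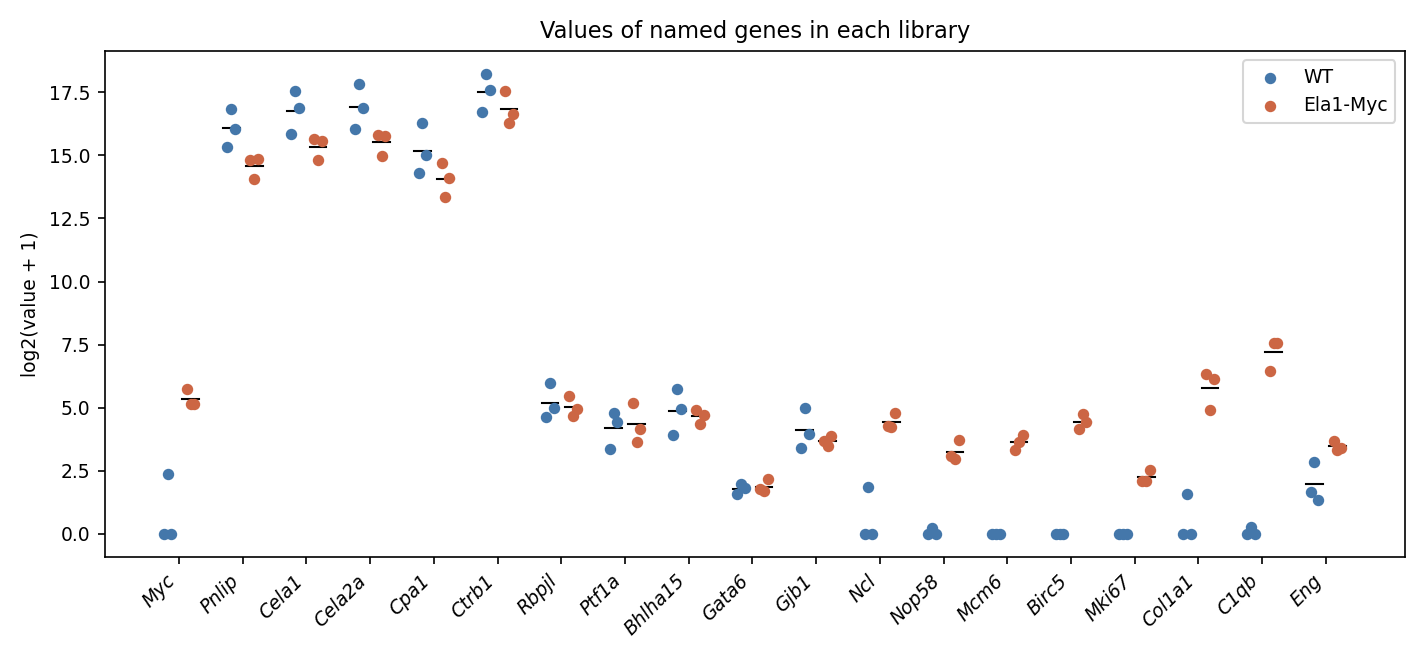
Values of named genes as log2(value + 1), 1 point per library; black lines are group means on that scale, left out for a group with a library listed at 0. The enzymes Pnlip, Cela1 and Cela2a are lower in Ela1-Myc, while Mcm6, Birc5 and Mki67 are at 0 in all 3 WT libraries and above 0 in all 3 Ela1-Myc libraries.

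Most metabolic and chaperone genes were higher on the deposited scale, apart from those of oxidative phosphorylation. Higher members numbered 16 of 17 for glycolysis (16 adjusted over the list alone), 34 of 34 for the mitochondrial ribosome and import (34), 22 of 24 for cholesterol and fatty acid synthesis (23), 18 of 38 for oxidative phosphorylation (11) and 19 of 20 for cytosolic chaperones (19), with none lower. After scaling the higher members were 10, 10, 7, 0 and 12. Members listed at 0 in at least 1 WT library numbered 8, 8, 10, 2 and 13. Among those above 0 in all 6 libraries, 5 of 9, 6 of 26, 1 of 14, 2 of 36 and 3 of 7 were higher after scaling. Only oxidative phosphorylation had lower members there, 2 of 36. Camera placed glycolysis, the mitochondrial ribosome, cholesterol synthesis and the chaperones above other genes (adjusted p = 0.00338, 0.0203, 0.0333 and 0.00357) and oxidative phosphorylation below them (adjusted p = 0.0187, against a median of 1.504). After scaling the first 4 adjusted p were 0.00141, 0.00142, 0.0611 and 0.000778 and that of oxidative phosphorylation was 0.42, so cholesterol synthesis and oxidative phosphorylation lost the call; with an estimated correlation the adjusted p were 0.817, 0.911, 0.817, 0.817 and 0.925. Oxidative phosphorylation lay above other genes without WT replicate 2 (adjusted p = 0.00888), where cholesterol synthesis was not called (adjusted p = 0.148); without Ela1-Myc replicate 1 the mitochondrial ribosome, cholesterol synthesis and chaperones were not called (0.37, 0.138 and 0.171), nor without WT replicate 3 the mitochondrial ribosome and cholesterol synthesis (0.067 and 0.293). The phosphofructokinase Pfkp went from 0.306 ± 0.0642 to 5.28 ± 0.576 (SD, n = 3 each), by 2.26 log2 units (adjusted p = 2.45e-05; 0.00653 after scaling). Lactate dehydrogenase Ldha was listed at 0 in WT replicates 1 and 3, was at 15.1 in WT replicate 2 and at 104.2, 152.2 and 118.5 in Ela1-Myc. The sterol regulator Srebf2 and the co-chaperone Stip1 were listed at 0 in the same WT replicates and passed on both scales.

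Markers of macrophages and of the stroma were called higher in Ela1-Myc than in WT. All 22 tested macrophage and dendritic cell markers rose on the deposited scale (22 adjusted over the list alone; median 4.75) and 16 after scaling (median 3.54), none lower; 20 of them were listed at 0 in at least 1 WT library. Only 2 were above 0 in all 6 libraries, of which 2 were higher after scaling. The complement gene C1qb was at 87.0, 190.6 and 190.4 in Ela1-Myc and at 0.202 in WT replicate 2, and listed at 0 in WT replicates 1 and 3, and Cd68 and Ctss were listed at 0 in all 3 WT libraries. Of 27 stellate cell, fibroblast and matrix markers 26 rose (27 adjusted over the list alone; median 2.56), and 12 after scaling (median 1.61). Of these markers, 12 were listed at 0 in at least 1 WT library. Among the 15 above 0 in all 6 libraries, 4 were higher and none lower after scaling, with a median of 0.651. Collagen Col1a1 was at 78.8, 28.7 and 69.5 in Ela1-Myc and 1.97 in WT replicate 2, and listed at 0 in WT replicates 1 and 3, and periostin Postn was listed at 0 in all 3 WT libraries. Endothelial markers, none of them at 0, numbered 9 higher of 15 (8 adjusted over the list alone; median 0.82), and 1 lower with none higher after scaling (median -0.22); Egfl7 rose by 2.09 log2 units (adjusted p = 0.00108; 0.0624 after scaling). Camera placed the macrophage and stellate lists above other genes (adjusted p = 4.87e-08 and 0.000624; 1.12e-07 and 0.000304 after scaling; 0.813 and 0.817 with an estimated correlation) and did not place the endothelial list apart.

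Duct and progenitor genes were mixed. Of 19 duct markers 13 were higher (13 adjusted over the list alone; median 2.15), and after scaling 6 were higher and 2 lower. Keratin Krt19 went from 6.65 ± 5.61 to 19.9 ± 5.63 (SD, n = 3 each), by 1.65 log2 units (adjusted p = 0.0215; 0.54 after scaling). Sox9, a progenitor and duct factor, was not called, with 0.42 (adjusted p = 0.187) turning to -0.46 after scaling (adjusted p = 0.107); it was called lower under quantile normalization (adjusted p = 0.0101) and higher with array weights (0.0469). Of 14 progenitor and embryonic factors 10 were higher (10 adjusted over the list alone), and after scaling none was higher and 2 were lower. Camera did not place either list apart from other genes.

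**Figure D3:**
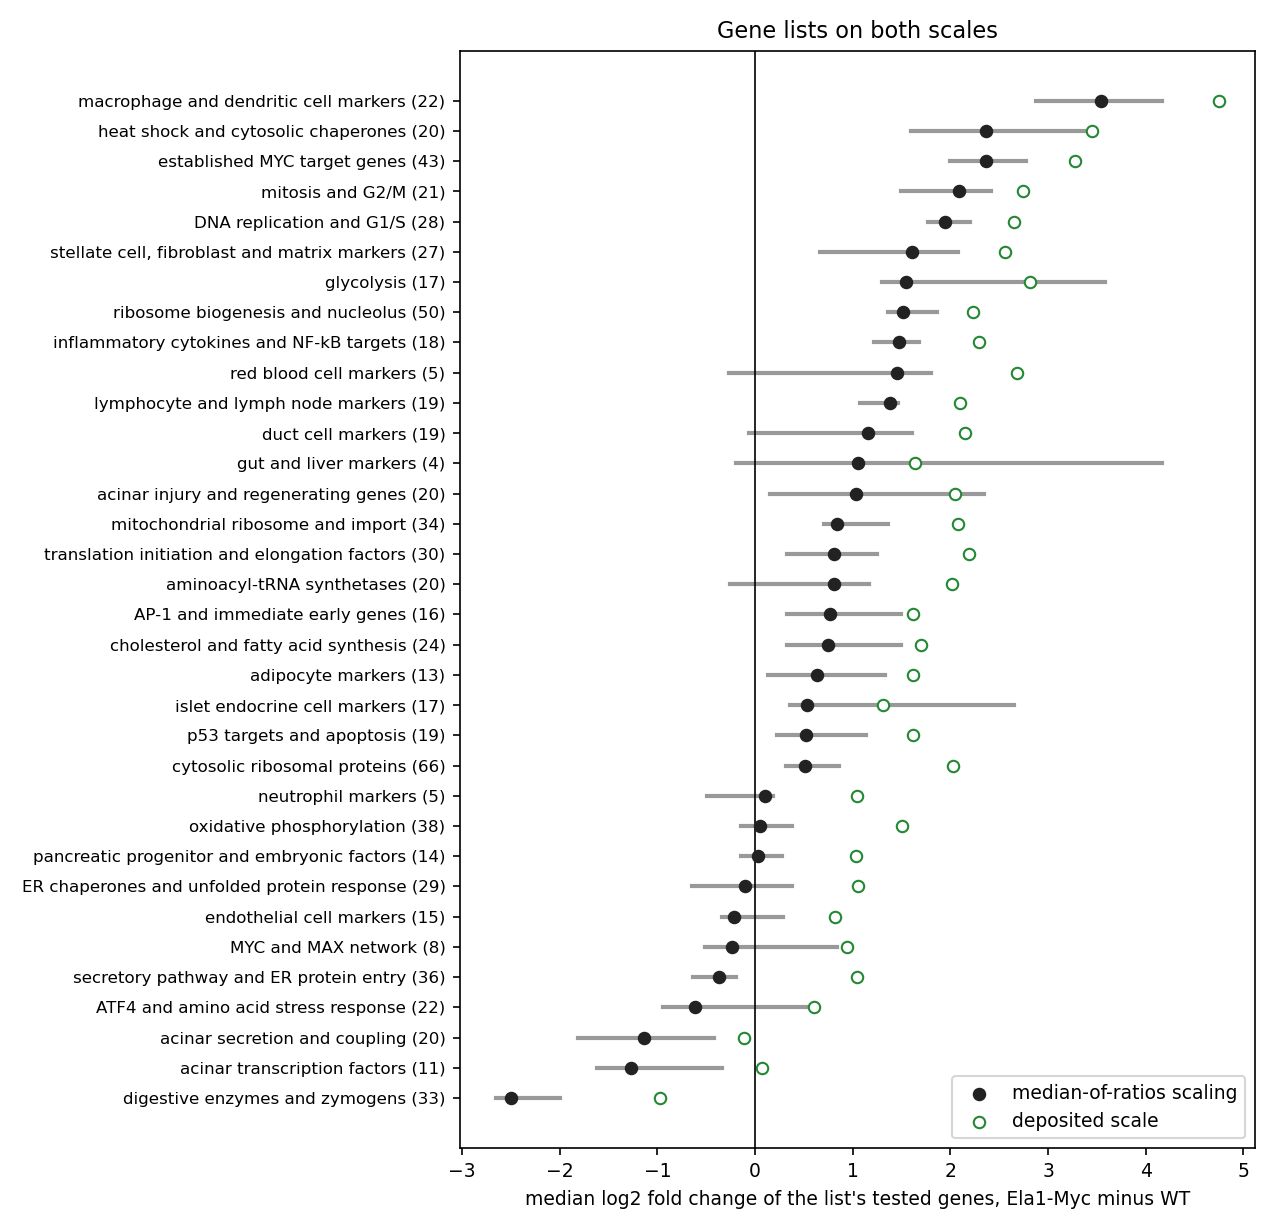
Median log2 fold change, Ela1-Myc minus WT, of the tested genes of each list (number of genes in parentheses) on the deposited scale (open circles) and after median-of-ratios scaling (filled circles); grey bars are 95% bootstrap intervals over the list's genes for the filled circles. The digestive enzyme list lies lowest on both scales (-0.98 and -2.50) and the macrophage list highest (4.75 and 3.54).

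Inflammatory and immediate early genes were among those that rose, while injury genes were higher about as often as tested genes at large. All 18 inflammatory cytokine and NF-kB target genes were higher (18 adjusted over the list alone), 10 of them after scaling, as were 14 of 16 AP-1 and immediate early genes (15), 6 after scaling, with none lower. Listed at 0 in at least 1 WT library were 13 inflammatory and 7 AP-1 genes. Among those above 0 in all 6 libraries, 3 of 5 and 0 of 9 were higher after scaling. Camera placed both lists above other genes (adjusted p = 6.25e-05 and 0.0202; 0.000304 and 0.0278 after scaling; 0.817 for each with an estimated correlation), but not without WT replicate 2 (adjusted p = 0.175 and 0.16). The chemokine genes Ccl2 and Cxcl16 and the early growth response gene Egr1 passed on both scales; Ccl2 and Egr1 were listed at 0 in all 3 WT libraries and Cxcl16 in WT replicates 1 and 3. Of 20 acinar injury and regenerating genes 14 were higher (14 adjusted over the list alone), and after scaling 7 were higher and 4 lower, with no camera call. The 14 of 20 lay close to the share of all tested genes, 6182 of 8802. Among the 11 members above 0 in all 6 libraries, 1 was higher and 4 were lower after scaling, with a median of -0.019. Reg3g stood at 0.914 in WT replicate 2 and at 32.3, 49.7 and 43.0 in Ela1-Myc, and was listed at 0 in the other 2 WT libraries. The galectin gene Lgals3, listed at 0 in all 3 WT libraries, stood at 16.8, 26.2 and 32.0. Reg3b, listed at 0 in WT replicate 1, passed on the deposited scale (adjusted p = 0.0231) and not after scaling (adjusted p = 0.307).

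The largest increases by the rule for named genes were all of genes listed at 0 in 2 or 3 WT libraries. Beside the enzyme copies Prss3, Prss1, Amy2a5 and Amy2b and the macrophage gene C1qb, they were the calcium-binding protein S100g (605.8, 197.1 and 165.0 in Ela1-Myc), apolipoprotein Apoe (404.9, 915.4 and 750.1), corticosteroid-binding globulin Serpina6 (198.6, 170.9 and 151.3), matrix Gla protein Mgp (246.0, 505.5 and 387.0), ribosomal protein Rpl37a (674.4, 638.5 and 476.8), tubulin Tuba1b (137.0, 213.5 and 159.4) and vitamin D-binding protein Gc (233.0, 69.7 and 48.5). S100g, Serpina6 and Gc were listed at 0 in all 3 WT libraries. Rpl37a and Prss1 did not pass after scaling (adjusted p = 0.0722 and 0.0569); the other 10 did.

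The decreases that met the rule were 7 genes of the enzyme list and 3 others. The respiratory chain gene Ndufs5 went from 24.7 ± 11.5 to 8.37 ± 1.97 (SD, n = 3 each), by -1.37 ± 0.573 log2 units (SE; adjusted p = 0.0445), or -2.75 after scaling. Epidermal growth factor Egf fell by 1.06 (adjusted p = 0.0384) and the kallikrein pseudogene Klk1b7-ps by 0.96 log2 units (adjusted p = 0.0388), or by 2.29 and 2.17 after scaling. Among genes above 0 in all 6 libraries after scaling, a group chosen after the values were seen, 735 were higher and 781 lower of 6995. Its largest changes included increases of the detoxifying hydrolase Ephx1 (2.55) and the secreted protein Fstl1 (2.31), and decreases of lipase Pnliprp2 (-2.93), zymogen granule protein Gp2 (-2.87) and the amino acid transporter Slc38a5 (-2.87), which Ela1-Myc libraries held at 39.6, 19.9 and 34.3 against 64.5, 152.5 and 52.6 in WT. On the deposited scale Ephx1 and Fstl1 passed (adjusted p = 0.000182 and 0.000112), while Pnliprp2, Gp2 and Slc38a5 did not.

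The WT libraries were less alike than the Ela1-Myc libraries, which limits all of these comparisons. Pearson correlations of log2 values across the tested genes, which are not independent replicates, were 0.845 to 0.876 between WT libraries and 0.913 to 0.958 between Ela1-Myc libraries. Between the groups they were 0.598 to 0.822 for 8 of the 9 pairs and 0.876 for WT replicate 2 and Ela1-Myc replicate 1.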

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

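The 6203 changed, 6182 higher and 5207 at least 2-fold changed genes stayed within 1.5 times (4554 to 8507, 4549 to 8482 and 3633 to 6134) with a pseudocount of 0.1, no filter, robust and array-weighted fits, genes above 0 in all libraries, zeros as missing, small RNA genes removed and each library left out. No filter tested 23099 genes, so its 8507 changed genes were a smaller share than 6203 of 8802. For the other settings, unless stated, the cause was not tested. A minimum mean of 5, which tests 3162 genes, left 1750 changed, 1742 higher, 8 lower and 1750 at least 2-fold. Median-of-ratios scaling gave 2320, 1614, 706 and 1750, the same without WT replicate 2 2485, 1845, 640 and 2094, and scaling of the 6995 genes above 0 in all libraries 1516, 735, 781 and 854. Quantile normalization gave 2754, 996, 1758 and 1695, removal of the enzymes with equal totals 2425, 2123, 302 and 2165, and a pseudocount of 1 on the deposited scale 3375, 3369, 6 and 3371. RIN as a covariate gave 4013 changed and 3998 higher genes, and a pseudocount of 5 left 1847 at least 2-fold, since it shrinks log2 changes. The 21 lower genes became 13 in a robust fit, 132 with array weights and 34 with zeros as missing. Leaving out 1 library gave 4554 to 7125 changed, 4549 to 7113 higher, 5 to 62 lower and 3955 to 6134 at least 2-fold. The mean of Myc in Ela1-Myc went from 40.2 to 23.06 after scaling.

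With each library left out, 18 to 22 lists passed and all 6 main lists kept call and direction, with adjusted p of at most 2.97e-18 for enzymes, 0.000141 for acinar transcription factors, 3.25e-09 for ribosome biogenesis, 0.00357 for MYC targets, 8.18e-08 for replication and 5.13e-06 for mitosis. The 19 lists past the threshold became 9 with the pseudocount on the deposited scale, 12 with genes above 0 in all libraries, and 0 with an estimated correlation, with or without scaling. With it the adjusted p was 0.813 for enzymes, acinar transcription factors, ribosome biogenesis, replication and mitosis and 0.817 for MYC targets, and 0.467 and 0.711 with scaling. Enzymes lost the call under quantile normalization (0.271), acinar transcription factors without a filter (0.452), and ribosome biogenesis with the pseudocount on the deposited scale (0.0566). MYC targets lost it there (0.253), with genes above 0 in all libraries (0.192; 0.0661 with scaling) and with zeros as missing (0.134). In the other direction lay the secretory pathway without a filter (0.348) and without WT replicate 2 (0.901, against as low as 5.47e-06 without another library) and ER chaperones without a filter (0.961). Oxidative phosphorylation did so without a filter (0.0407), under quantile normalization (0.434) and with array weights (0.472). It also did so without WT replicate 2 (0.00888, and 0.355 with scaling), with the pseudocount on the deposited scale (1) and with scaling of genes above 0 (0.804). Over all libraries left out its adjusted p was 0.00192 to 0.0225, in the other direction only without WT replicate 2. Other lists lost the call as follows. With a pseudocount of 0.1: oxidative phosphorylation (0.174), mitochondrial ribosome (0.106), cholesterol synthesis and chaperones (0.122 each); with no filter: acinar secretion (0.0787) and ATF4 (0.782); with a minimum mean of 5: oxidative phosphorylation and cholesterol synthesis (0.672 each) and AP-1 (0.578). After scaling: oxidative phosphorylation (0.42) and cholesterol synthesis (0.0611); under quantile normalization: ER chaperones (0.188), ATF4 (0.192) and AP-1 (0.0532); without the enzymes: oxidative phosphorylation (0.787) and cholesterol synthesis (0.0885). With array weights: the secretory pathway (0.472), ER chaperones (0.139) and AP-1 (0.119); with RIN: mitochondrial ribosome (0.182), cholesterol synthesis (0.124) and AP-1 (0.0846). With the pseudocount on the deposited scale: the secretory pathway (0.0531), glycolysis (0.181), mitochondrial ribosome and AP-1 (0.126 each), cholesterol synthesis (0.77), stellate markers (0.0724) and chaperones (0.956). With genes above 0: oxidative phosphorylation (0.284), cholesterol synthesis (0.264), AP-1 (0.292) and chaperones (0.302), and with scaling the last 3 (0.25, 0.385 and 0.163). With zeros as missing: oxidative phosphorylation (0.143), cholesterol synthesis and chaperones (0.112 each) and AP-1 (0.134); after scaling without WT replicate 2: ER chaperones (0.373), ATF4 (0.17) and cholesterol synthesis (0.132). The 15 lists without a call had 350 camera tests in alternatives, 96 in the other direction and 33 past the threshold, in 10 of the lists. Ribosomal proteins lay below other genes at 0.000969 with a pseudocount of 5 and above them at 0.000118 under quantile normalization. Lymphocyte markers lay above other genes at 6.36e-13 with RIN, and below them at 0.013 without WT replicate 2 and at 0.0309 with zeros as missing. Fry, which tests a list's own genes against no change and not against other genes, did not call enzymes (lower, 0.421), acinar transcription factors (higher, 0.704), acinar secretion (higher, 0.76), the secretory pathway (higher, 0.141), ER chaperones (higher, 0.271), ATF4 (higher, 0.246) or oxidative phosphorylation (higher, 0.0826), and called 8 of the 15 lists without a camera call.

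Of 93 genes named with a result, 80 were called. Of these, 80 kept call and direction with a pseudocount of 5 or array weights, 71 with a pseudocount of 0.1, 64 without a filter, 66 in a robust fit, 69 with RIN, 61 after scaling (65 without WT replicate 2), 52 under quantile normalization, 44 with the pseudocount on the deposited scale, and 64 to 74 with 1 library left out. Log2 changes in the other direction came from scaling for Ptf1a (-1.273), Nr5a2 (-0.6381), Gata4 (-0.01864), Gata6 (-1.005), Sox9 (-0.4603) and Odc1 (-0.3795), equal among genes above 0, and without WT replicate 2 for Ptf1a (-1.284), Nr5a2 (-0.5112), Gata6 (-1.164), Sox9 (-0.5482), Odc1 (-0.1828) and Foxp1 (-0.05551). Quantile normalization turned Ptf1a (-1.438), Nr5a2 (-0.9829), Gata4 (-0.3027), Gata6 (-1.391), Sox9 (-0.9605), Odc1 (-0.4849), Foxp1 (-0.4778), Snap23 (-0.1125), Itpr3 (-0.3091) and Prss2 (0.2614), and removal of the enzymes Ptf1a (-0.9379), Nr5a2 (-0.3909), Gata6 (-0.7729), Sox9 (-0.2535) and Odc1 (-0.02175). RIN turned Ptf1a (-0.5752), Nr5a2 (-0.06862) and Gata6 (-0.02204), and array weights Ptf1a (-0.1834) and Rbpjl (0.0009427). With 1 library left out the changes ranged over both signs for Ptf1a (-0.2768 to 0.4981), Rbpjl (-0.4345 to 0.2452), Bhlha15 (-0.6738 to 0.2262), Gata6 (-0.06943 to 0.17) and Gjb1 (-0.7662 to 0.01845).

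No paired analysis was possible because the labels carry no replicate numbers, and those used here follow the order of the samples. Scaling to spike-in RNA and the fits for read counts were not run. With the depth of the libraries unknown, low genes and zeros cannot be given a detection limit.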

Other observations

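The tests of the listed zeros and of the scale of single libraries were chosen after their results had been seen, as was the check of the cell type lists on members above 0.

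The remaining lists had fewer higher genes after scaling than on the deposited scale, apart from red blood cell markers, which had 0 on both. Among p53 targets and apoptosis genes 15 of 19 were higher in Ela1-Myc (16 adjusted over the list alone), 6 higher and 1 lower after scaling. Trp53 stood at 0.184 and 1.27 in WT replicates 1 and 2 and at 16.24, 27.26 and 19.96 in Ela1-Myc, was listed at 0 in WT replicate 3, and passed on both scales (adjusted p = 9.69e-06 and 0.00305). The pro-apoptotic gene Bax and the cell cycle inhibitor Cdkn1a passed on both scales as well (after scaling adjusted p = 0.0212 and 0.0497); Bax was listed at 0 in WT replicates 1 and 3 and Cdkn1a in WT replicate 3. Islet markers were higher for 12 of 17 genes (13 adjusted over the list alone) and for 2 after scaling; insulin Ins2 stood at 1972 and 321.5 in WT replicates 2 and 3, was listed at 0 in WT replicate 1, and stood at 1950, 2152 and 2381 in Ela1-Myc. Glucagon Gcg stood at 100.4 in WT replicate 2 and at 175.8, 324.3 and 468.2 in Ela1-Myc, was listed at 0 in the other 2 WT libraries, and passed on the deposited scale only (adjusted p = 0.00178; 0.0684 after scaling).

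All 19 tested lymphocyte and lymph node markers were higher (19 adjusted over the list alone), but only 1 after scaling, and 17 of them were listed at 0 in at least 2 WT libraries. The leukocyte gene Ptprc stood at 2.28 in WT replicate 1, was listed at 0 in the other 2 WT libraries, and stood at 2.56, 17.2 and 17.1 in Ela1-Myc. Adipocyte markers were higher for 11 of 13 genes (12 adjusted over the list alone) and for 0 after scaling; adiponectin Adipoq stood at 25.1 and 0.718 in WT replicates 1 and 2 and at 13.8, 50.2 and 25.5 in Ela1-Myc, and was listed at 0 in WT replicate 3. Neutrophil markers were higher for 1 of 5 genes, red blood cell markers for 0 of 5, gut and liver markers for 3 of 4 and nerve markers for 1 of the 2 tested, and for 0, 0, 2 and 0 after scaling. Camera placed none of these lists apart from other genes on the deposited scale or after scaling, and the nerve list was too short for it.

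Abundant genes listed at 0 in WT libraries were the first pattern weighed. The genes with an Ela1-Myc mean of at least 10 numbered 2501. Among their 7503 WT values, exact zeros outnumbered values above 0 and below 0.3 by 9.18 to 1 (1101 against 120). A cutoff setting all low values to 0 would leave such a gap, but the rows sharing 1 value within each WT library argue against it. They kept 464, 822.5 and 173.9 on the deposited scale in WT replicates 1 to 3, far below 0.3 on the divided scale. Tested genes below that shared value numbered 1076, 605 and 1428, of which 1061, 592 and 1426 were at 0. Silence in the WT pancreas as the cause of the whole pattern is argued against by the other WT libraries: of the 668 genes with a 0 in a WT library, 81.1% (542) had a value of at least 1 in another WT library, and 36.5% (244) had one in WT replicate 1 or 3. For the 86 genes at 0 in all 3 WT libraries silence stays open. Earlier forms of this test used gene lists, with 0 of 66 cytosolic ribosomal proteins and then 40 of 117 nucleolus, glycolysis, chaperone and translation factor genes at 0 in 2 or more WT libraries. An adjustment by the authors may have produced zeros, and what the genotype adds to them was not tested.

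The excess of higher genes on the deposited scale was the second pattern. If a smaller enzyme share alone left more of the total to other genes, removing the enzymes and equalising totals would bring the median gene to about 0; it lay at 0.504, against 1.22 before, which is between the bounds set for and against this explanation. The log2 scale factors ranged over 1.2 among WT libraries and over 0.343 among Ela1-Myc libraries, against a difference of 1.52 between group means, so the spread in scale within WT cannot be told apart from part of the shift. A true change in RNA content of the tissue stays open as well, since spike-in values were not used here. With 3 libraries per group there are 10 splits, too few for a share under 0.05: the real split, 1 of the 10, gave 6203 changed genes, 6182 higher, 21 lower and 5207 changed at least 2-fold, and the highest of the other splits gave 0 for each.

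Lower enzymes together with higher markers of other cell types, relative to the median gene, were the third pattern. A lower share of acinar cells alone would raise the markers of all other cell types alike. The highest and the lowest list median after scaling differed by 3.76, between macrophage (3.54, 95% bootstrap interval over genes 2.88 to 4.17) and endothelial markers (-0.22, -0.343 to 0.284). Because zeros reach 20 of the 22 macrophage markers, the medians were also taken over members above 0 in all 6 libraries, where 15 stellate and 15 endothelial markers lay at 0.651 (0.386 to 1.16) and -0.219 (-0.332 to 0.342). The lists were compared as extremes, the intervals are over genes, and the log2 scale understates the change of low genes. Unequal medians therefore do not exclude a lower share of acinar cells as part of the pattern. With RIN as a covariate the enzyme median after scaling was -2.85 (-2.93 to -2.38), against -2.50 without it. This fit cannot exclude RNA integrity as a cause. RIN spanned only 7.1 to 7.3 in WT, so its slope rests mostly on the Ela1-Myc libraries. The interval is over genes and does not measure the spread between libraries. An effect of the Myc transgene in acinar cells, with more macrophages and stroma, stays a hypothesis, and the authors' adjustment of the values is not excluded as a contributor.

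The number of gene lists past the camera threshold does not single out the genotype. The real split gave 19 lists, the highest other split gave 20, and 3 of the 10 splits, the real one included, gave at least as many; 10 splits are too few for a share under 0.05. The other 9 splits gave between 12 and 20 lists. For the digestive enzymes, acinar transcription factors, acinar secretion, ribosome biogenesis, DNA replication and mitosis lists the real split had the smallest camera p of the 10 on both scales, but on the deposited scale another split came close for enzymes (1.32e-42 against 3.86e-43) and acinar transcription factors (2.07e-06 against 5.96e-07). For mitosis and replication this rank was largely fixed by the filter, with 21 of 21 and 22 of 28 tested members at 0 in at least 2 WT libraries. It was so in part for ribosome biogenesis, with 23 of 50. Of the other lists that camera called on the deposited scale, the splits with a p as small, the real one included, numbered 2 for the stellate, macrophage and AP-1 lists (1 for each after scaling), 3 for MYC targets (4) and glycolysis (3), and 4 for the secretory pathway (4), ATF4 (5), mitochondrial ribosome (4), inflammatory (3) and cytosolic chaperone (4) lists. They numbered 5 for cholesterol synthesis (5), 6 for ER chaperones (6) and 7 for oxidative phosphorylation (9).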
